A study of Homo sapiens with 23 samples.

How the data were processed

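RNA of human breast cancer cells was measured on 23 spotted cDNA arrays (CNIO Oncochip) that take 2 colours each. Per the labels, cells were given the vehicle DMSO or 9-tetrahydrocannabinol (THC, the main psychoactive cannabinoid of cannabis) at 3 or 5 µM for 8 or 24 h, and the other channel of every array held untreated cells of the same experiment collected when the drug was added (0 h). Each of the 6 groups had 2 experiments, and each experiment was hybridised once with the sample in Cy3 and once in Cy5 (a dye swap), except 3 µM THC at 8 h in experiment 1, of which only the Cy5 array was analysed here. The pair of arrays shares its extracts, so it counted as 1 replicate, which gave 12 replicates from 23 arrays. The labels name 2 experiments but do not say how the cultures were kept, so the p-values measure the spread between these experiments.

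The deposited scanner files hold raw spot intensity, which per the file headers is the foreground mean and the local background median of each spot at 532 nm (Cy3) and 635 nm (Cy5), with neither background subtracted nor arrays normalized. Per the design text, slides were scanned on a Scanarray 5000 XL and quantified with GenePix Pro 6.0. Each file lists 27648 spots in 48 print blocks, with the GenePix flag of each spot (0, -50 for not found, -100 for bad), a clone name and a spot ID. The authors also deposited a table of log2 ratios of the same arrays, with scale, centring and direction unstated. Set against the scanner values, each of its columns matched a log2 ratio after background subtraction and print-tip loess on the spots with flag 0, with an absolute correlation of at least 0.97 and absolute slopes between 0.987 and 1. Its column medians lay between -0.034 and 0.038. Scale and centring were thereby settled for all columns. Direction was settled by channel, Cy5 over Cy3 on 11 arrays and Cy3 over Cy5 on 12. By the labels that is sample over reference on 10 arrays and reference over sample on 13, for which no source used here gives a reason. In 9 of the 11 dye-swap pairs the columns ran opposite ways by channel.

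Values were computed in R 4.3.3 with limma 3.58.1. Background was corrected with normexp at an offset of 50, log2 ratios were normalized by loess within each array, spots flagged bad were left out, and the spots of one ID were averaged. Only ID classes h and ch were tested (26646 and 304 spots, 11675 clone IDs, against 9726 clones stated in the design text). The 194 blank spots and 2 further ID classes of 152 and 352 spots stayed out of the loess and the tests. The rule fixed before the data were examined for calling a clone above background used the foreground median and the background SD of each spot, neither of which the files used here hold. In its place a clone was tested when its mean foreground minus background exceeded the median of the blank spots by 2 robust SDs in either channel on at least 4 arrays, which 11186 clones met. A share of 10.9% to 51.4% of the spots of an array carried flag 0 (median 15.6%), the rest being mostly not found by the quantification program. The number of arrays limits the precision.

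The 2 readings of the arrays described next were carried through all comparisons. As labelled, every array was turned to sample over 0 h reference by its dye label, a dye effect of each clone estimated on the complete pairs was removed, and the 2 arrays of a replicate were averaged. As headed, every array was left as Cy5 over Cy3 by its channel headings and no array was turned. The reading as labelled was fixed before the data were examined and gives the main values. The reading as headed was chosen after seeing the data, because the 2 arrays of every pair ran opposite ways. Its values have a sign but no settled direction, and are called positive or negative in place of higher or lower. If headings and dye labels are both right, sample against reference cancels between the 2 arrays of a pair as headed. What then stays is a dye effect, and clones called as headed would not be changes of expression.

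Group means were fitted with lmFit and eBayes over all 12 replicates, with 6 residual degrees of freedom, two-sided, and p-values were adjusted by Benjamini-Hochberg over all clones tested, with an adjusted p threshold of 0.05. THC over both doses and times was fitted as time plus treatment. The experiment number is a shared experiment with its own 0 h reference in the labels, so it pairs the samples; it entered as a block in an alternative. Checked on the values, the deviations of the 2 experiments of a group correlated at over 0.1 in 4 of the 15 pairs of groups as labelled (median 0.029) and in 13 of the 15 as headed (median 0.52). On simulated data for 5 µM THC against vehicle at 24 h with 11157 clones, 88% of 2-fold and 98% of 4-fold changes were recovered as labelled, with 9 false calls. As headed with the block it was 76% and 91%, with 7 false calls. The simulated changes were added to replicate means, so the 2 arrays of a pair could not run opposite ways. Where they do, as described below, a change can cancel as labelled, so these shares do not apply to the counts as labelled.

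Neither clone names nor spot IDs are paired with genes in the sources used here: 0 of them equal any of the 59778 gene symbols of the reference table, which was therefore not used for names. The rule for named genes, fixed before the data were examined, takes only clones with a gene symbol (the 12 largest rises and 12 largest falls past the threshold, filled to 10 by smallest p), so it named none. The gene lists written beforehand, JUND among them, the test at gene level and a slide or scan batch could not be run. At most 2 clones of each sign per comparison are named by their IMAGE clone number, all chosen after their values were seen: among those past the threshold as headed and of one sign in both experiments, those of largest size. Correlations across clones describe the arrays, since clones are not independent replicates. Alternatives covered background correction, normalization, filters, flags, dye effect, arrays as separate values, Cy5 arrays alone, the groups in the fit, the authors' log2 table, array weights and each replicate left out. Columns of the authors' log2 table were turned to sample over reference as labelled and to Cy5 over Cy3 as headed. Only where the authors' own signs are named were they left as deposited.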

Results

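Expression of spotted clones was measured in human breast cancer cells after vehicle or THC at 3 or 5 µM for 8 or 24 h, each against untreated cells of the same experiment at 0 h. The 6 groups held 2 replicates each, from 2 experiments. Between 5460 and 11084 of the 11675 clones exceeded the blank spots on an array, and 4865 did so on all 23 arrays. The lowest number was that of the 3 µM THC array at 24 h in experiment 1 with the sample in Cy3. On that array the blank spots themselves carried signal, with a median of 234 intensity units above background in the Cy5 channel, against at most 3.5 on the other arrays. In 8 of its 48 print blocks, spot brightness correlated at -0.098 to 0.085 with the mean of the other arrays. Over all 1104 blocks of all arrays the median correlation was 0.97, and 11 blocks on 4 arrays lay under 0.5.

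**Figure D1:**
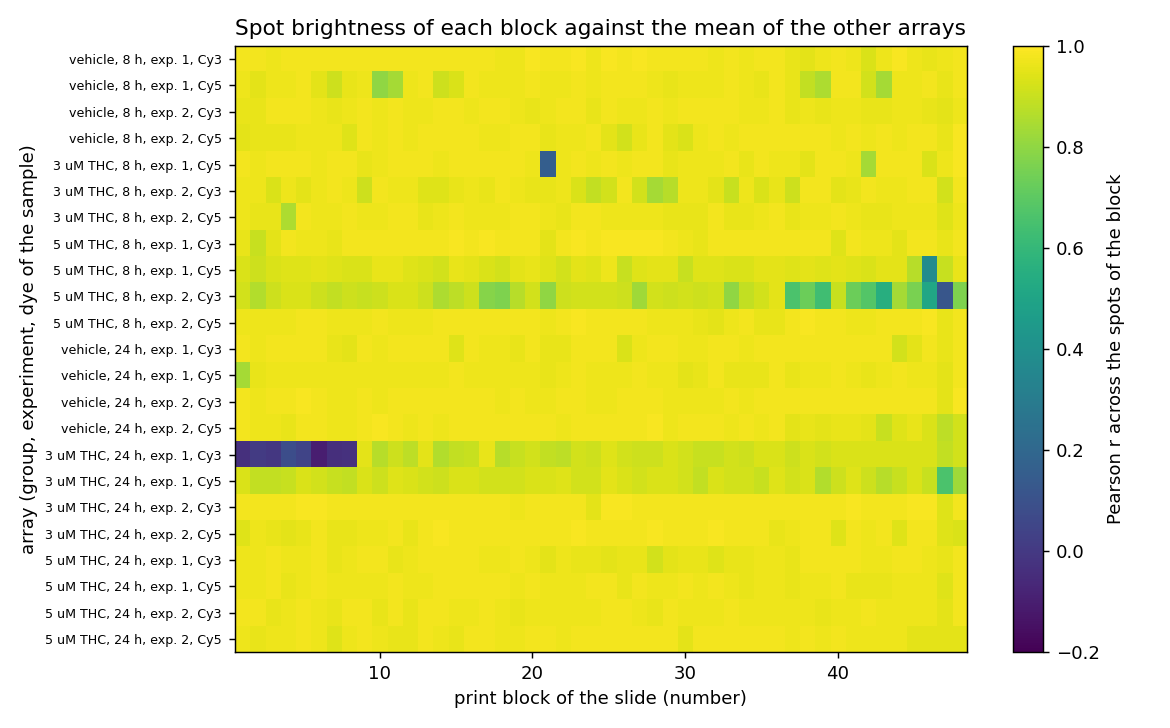
Pearson correlation of log2 spot brightness (both channels added) between each print block of an array and the same block averaged over the other arrays. Rows are the 23 arrays and columns the 48 blocks. The 8 dark blocks of the 3 µM THC array at 24 h in experiment 1 lie between -0.098 and 0.085, against a median of 0.97 over all blocks.

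The swap of dyes between the 2 arrays of a replicate should leave the ratio of sample to 0 h reference unchanged once each array is turned by its label. The 2 arrays of a pair instead ran opposite ways in all 11 pairs, with correlations across the tested clones between -0.76 and -0.17 (median -0.42). Over the 1983 clones with a spot of flag 0 on at least 12 arrays they lay between -0.83 and -0.32. A dye effect that a clone has on every array cancels in a difference of THC and vehicle taken within one dye. That difference, too, ran opposite ways between the Cy5 and the Cy3 arrays in all 7 cases where both could be had, with correlations between -0.89 and -0.23. For 5 µM THC at 24 h it was -0.81 in experiment 1 and -0.89 in experiment 2. The median background was also lower in the channel labelled as the sample on 19 of the 23 arrays, whichever wavelength heads it. Each comparison is given below as labelled and as headed.

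**Figure D2:**
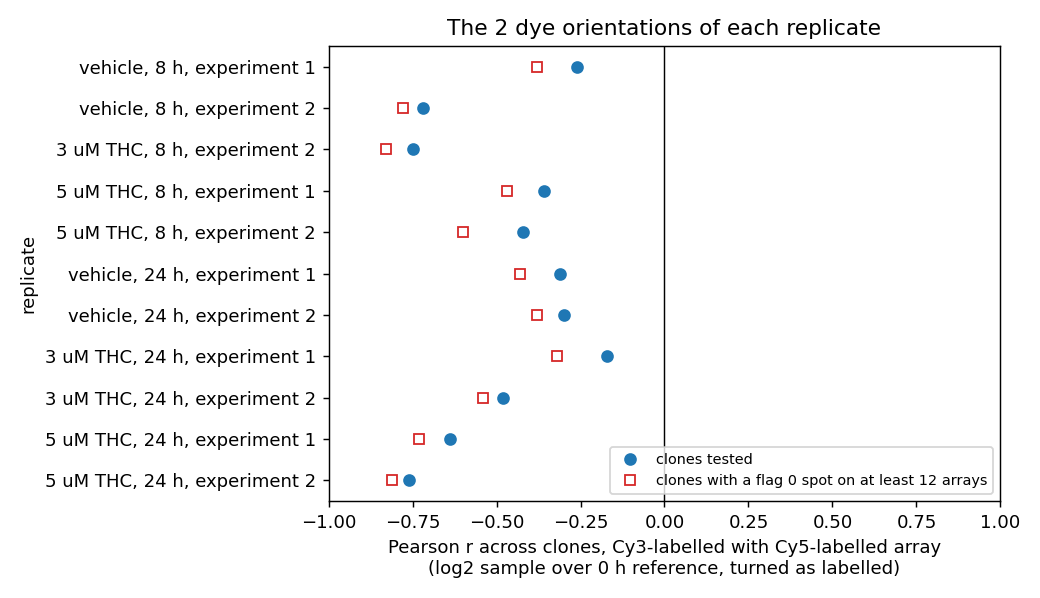
Pearson correlation across clones between the array with the sample in Cy3 and the array with the sample in Cy5, both turned to log2 sample over 0 h reference as labelled, for each of the 11 replicates with both arrays. Circles are the tested clones and squares the 1983 clones with a spot of flag 0 on at least 12 arrays. All values lie below 0.

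Among the 121 pairs of arrays of different replicates with the sample in the same dye, which need no turning, 1 pair correlated at under -0.3. It was vehicle at 8 h in experiment 2 and 5 µM THC at 8 h in experiment 1, both with the sample in Cy5, at -0.45. Over the 1983 clones with a spot of flag 0 on at least 12 arrays, 3 pairs lay under -0.3, all with the sample in Cy5. They were the same pair at -0.51, the 2 experiments of 5 µM THC at 8 h at -0.35 (-0.26 over all tested clones), and 3 µM THC in experiment 1 with 5 µM THC in experiment 2, both at 8 h, at -0.31. The direction by label was kept because the labels state the dyes, but the pair of 5 µM THC at 8 h holds the same condition in the same dye, so its direction is not settled. Each of the 4 arrays in these pairs was turned alone, a test chosen after the results were seen. The other array of its replicate, where there was one, was left as it was. Turning 1 array of a dye-swap pair that agreed as headed makes the pair cancel as headed and agree as labelled. The counts for groups with a turned array therefore follow in part from the turning and do not tell which direction is right. As labelled, 5 µM THC at 8 h then gave 5 clones with its experiment 1 turned and 11 with its experiment 2 turned. The other 6 comparisons of THC or dose stayed at 0 with any of the 4 turned. As headed with the block, turning either array of 5 µM THC at 8 h gave 0 clones at 5 µM and 8 h. Turning its experiment 1 or 2 gave 81 or 17 clones at 5 µM and 24 h, and 1 or 0 between the doses. Turning vehicle in experiment 2 or 3 µM THC in experiment 1 gave 181 or 150 at 5 µM and 24 h, 17 or 60 between the doses, and 4 each at 5 µM and 8 h.

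The comparison of 5 µM THC with vehicle at 24 h asked which transcripts the higher dose changed after a day. As headed, with the experiment as a block, limma placed 121 of 11185 clones past the adjusted threshold, 55 positive and 66 negative. This balance moved with the settings, to 69 and 42 with median centring, 27 and 61 with the authors' log2 table, 29 and 58 on clones with flag 0 on at least 12 arrays, and 117 and 54 without vehicle at 24 h in experiment 1. The largest positive difference was that of clone IMAGE:1049033, at 2.78 on the log2 scale (SE 0.13, adjusted p = 0.000687). Its mean was 2.81 ± 0.35 (SD, n = 2) with THC and 0.02 ± 0.12 (SD, n = 2) with vehicle. Clone IMAGE:208718 followed at 2.50 (SE 0.33), with 1.74 in experiment 1 and 3.26 in experiment 2. With the background subtracted, clone IMAGE:208718 had the larger difference of these 2, at 4.40 against 3.03 for clone IMAGE:1049033. It missed the threshold without the block (adjusted p = 0.0541), on the Cy5 arrays alone (0.0643), without the 4 brightest arrays (0.0678) and without vehicle at 24 h in experiment 2 (0.22). The largest negative differences were those of clone IMAGE:417504, at -2.45 (SE 0.26), and clone IMAGE:3528619, at -2.32 (SE 0.26). The authors' log2 table, with its columns turned to Cy5 over Cy3, put these 2 at -1.46 and -1.35. Clone IMAGE:417504 missed the threshold without experiment 2 of vehicle at 24 h (adjusted p = 0.127) or of 5 µM THC at 24 h (0.2). Clone IMAGE:3528619 missed it in these fits (0.12 and 0.211), without the block (0.0541), with the authors' table (0.0552) and without 5 µM THC at 24 h in experiment 1 (0.0507). The 4 brightest arrays were the Cy5 array of experiment 1 and the Cy3 array of experiment 2 of 5 µM THC at 8 h, and both arrays of experiment 1 of 3 µM THC at 24 h. Neither compared group thus lost an array without them. All 4 named clones exceeded the blank spots on all 8 arrays of both groups. Clones IMAGE:1049033 and IMAGE:208718 gave no value, however, with all negative flags left out or in the authors' log2 table. With these flags left out, 63 of the 121 clones could be measured, and 49 clones passed, 35 of them among the 121. As labelled, the 4 named clones differed by 0.02 (SE 0.26), -0.05 (SE 0.13), 0.10 (SE 0.11) and 0.10 (SE 0.15), in the order named. As labelled, limma placed 0 clones past the threshold, with 23 at an unadjusted p under 0.05, where chance alone would give 559. So low a count means that the p-values as labelled ran high here: the median SE was 0.10 against a median absolute difference of 0.035. With only the compared groups in the fit there were 175, and with array quality weights 244. The 0 is thus no evidence that nothing changed, and the same limit applies to counts far under 559 in the comparisons below.

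The differences of 5 µM THC and vehicle at 24 h in experiment 1 and experiment 2 correlated at 0.67 across clones as headed and at 0.01 as labelled. The 121 clones had a median absolute difference of 0.945 as headed and 0.05 as labelled. Each had the same sign on the Cy5 arrays and on the Cy3 arrays as headed, which means opposite signs by the labels. The clones were picked by their mean as headed, which largely fixes these values, so they are no test of either reading. On the Cy5 arrays alone, where both readings run the same way, 7 clones passed without the block and 17 with it, 16 of these among the 121. The count as headed changed with the block and with single replicates left out. Where that replicate belongs to a compared group, 1 remains there and the spread comes from the other groups. The count was 10 without the block, 3 without vehicle at 24 h in experiment 2, and 3 or 34 without 5 µM THC at 24 h in experiment 2 or 1. Leaving out either experiment of another group gave 40 for 3 µM THC at 24 h, 75 for 5 µM at 8 h, 78 for vehicle at 8 h and 202 for 3 µM at 8 h.

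**Figure D3:**
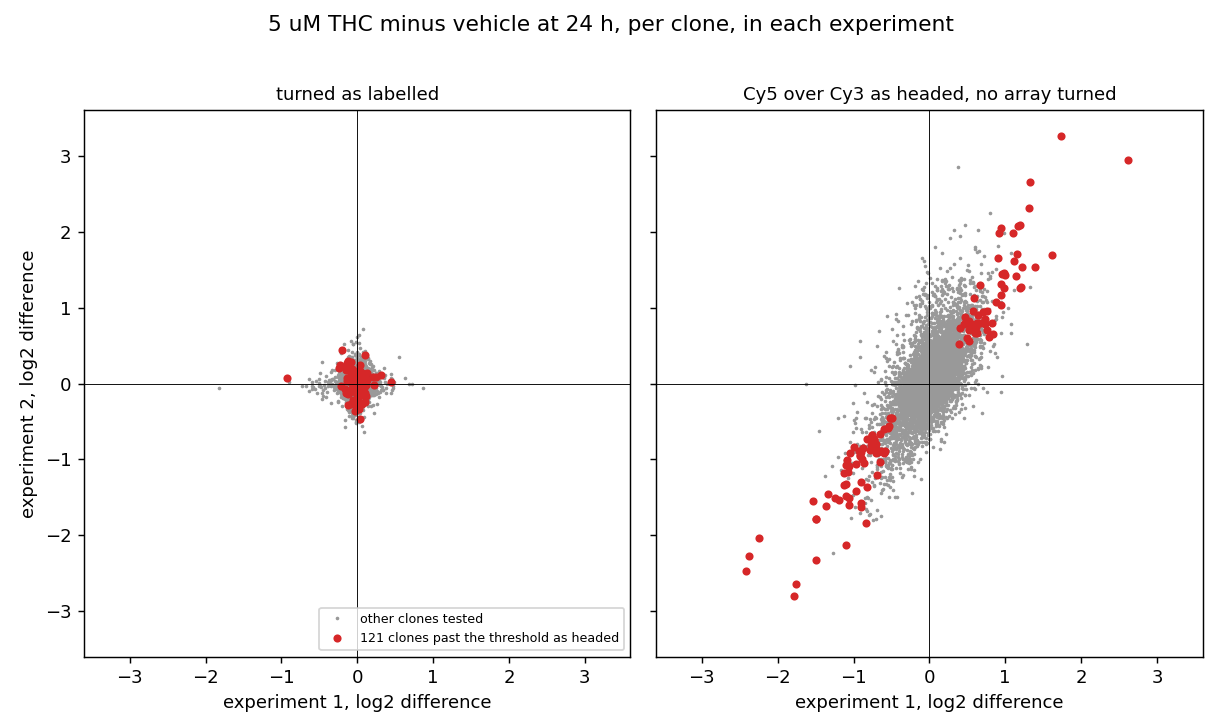
Difference of 5 µM THC and vehicle at 24 h (log2) for each tested clone in experiment 1 (horizontal) and experiment 2 (vertical), with arrays turned as labelled (left) and left as Cy5 over Cy3 (right). Red points are the 121 clones past the threshold as headed. The correlation across clones is 0.01 on the left and 0.67 on the right.

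At 3 µM and 24 h limma placed 0 of 11186 clones past the threshold in either reading. As headed, 2 clones passed with the background subtracted. At an unadjusted p under 0.05 there were 125 clones as labelled and 535 as headed with the block, where chance alone would give 559. The lowest adjusted p was 1 as labelled and 0.183 as headed with the block. The 2 experiments correlated at -0.05 as labelled and 0.46 as headed. Of the 121 clones called at 5 µM and 24 h as headed, 118 had the same sign at 3 µM and 24 h, with a median difference of 0.37 in the direction of the higher dose. Both doses share the vehicle replicates, so such likeness arises also with no effect at 3 µM. Its size under no effect was not computed for these clones, so the count and the median are no evidence of an effect at 3 µM.

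At 5 µM and 8 h, 5 clones passed as headed with the block, 3 positive and 2 negative, while median centring gave 4 and 26. The count was 0 with the background subtracted, without the 4 brightest arrays and with array quality weights. It was 7 positive and 33 negative with all negative flags left out, and 19 and 40 with the authors' log2 table turned to Cy5 over Cy3, each with 1 of the 5 among them. Clone IMAGE:4110925 differed by 1.18 (SE 0.11, adjusted p = 0.0371) and clone IMAGE:2326129 by 1.01 (SE 0.10, adjusted p = 0.0482). Clones IMAGE:853938 and IMAGE:782712 differed by -1.31 (SE 0.12) and -1.06 (SE 0.10), both with an adjusted p of 0.0371. Of these 4 clones, only IMAGE:853938 gave a value with all negative flags left out or in the authors' log2 table. As labelled these 4 clones differed by -0.06, 0.04, -0.20 and -0.07. In that reading 0 of 11184 clones passed, and 337 had an unadjusted p under 0.05. As labelled there were 59 clones without 5 µM THC at 8 h in experiment 2, 2 without its experiment 1, 5 without vehicle at 8 h in experiment 2, 12 without the 4 brightest arrays, and 1 on the Cy5 arrays alone. The 2 experiments correlated at 0.48 as headed and -0.43 as labelled. Without the block 0 clones passed as headed, and without vehicle at 8 h in experiment 1 there were 132. Left out in turn, experiment 2 of vehicle at 8 h, experiment 2 of 5 µM THC at 8 h or either experiment of vehicle at 24 h gave 0 as headed with the block. Experiment 1 of 5 µM THC at 8 h or either experiment of 3 µM at 24 h gave 1, which was not among the 5. Either experiment of 5 µM at 24 h gave 3, with 1 of the 5 among them, and either of 3 µM at 8 h gave 13, with 4.

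At 3 µM and 8 h no clone passed in either reading, while the Cy5 arrays alone gave 1 as labelled, and 1 as headed with the block. An unadjusted p under 0.05 was reached by 314 of 11184 clones as labelled and by 370 as headed with the block. This was the only one of the 4 comparisons in which the experiments correlated less as headed (-0.25) than as labelled (-0.09). The replicate of experiment 1 in this group rested on 1 array. Leaving out 3 µM THC at 8 h in experiment 2, which leaves that array alone in its group, gave 83 clones as labelled.

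Over both doses and times, THC changed 0 of 11186 clones as labelled, with 83 at an unadjusted p under 0.05, and 0 as headed with the block, with 724. Other settings as headed gave 13 clones with array quality weights, 3 with scaling between arrays, 2 among the clones with flag 0 on at least 12 arrays, and 1 each with the authors' log2 table and without vehicle at 8 h in experiment 2. The test of whether the THC effect differs between 24 h and 8 h gave 0 clones in both readings, with 40 at an unadjusted p under 0.05 as labelled and 1112 as headed with the block. As headed it gave 10 without vehicle at 24 h in experiment 1, 2 with the background subtracted, and 1 each with scaling between arrays and on the Cy5 arrays alone. The difference between the doses, averaged over both times, gave 0 clones as labelled (394 at an unadjusted p under 0.05) and 5 as headed with the block, 4 positive and 1 negative. Among these were clone IMAGE:1049033, at 1.42 (SE 0.09, adjusted p = 0.00773), clone IMAGE:4110925, at 0.83 (SE 0.08), and clone IMAGE:4101771, at -0.69 (SE 0.05). The mean of clone IMAGE:1049033 at 5 µM was 1.62 ± 1.39 (SD, n = 4) over both times, against 2.81 at 24 h alone. Its values thus lay far apart between the times, and its dose difference is no support separate from its call at 24 h. Without the block 2 clones passed, both positive, and clones IMAGE:1049033 and IMAGE:4101771 were not among them (adjusted p = 0.102 and 0.272). In that fit clone IMAGE:4110925 passed (0.0348), but it missed the threshold with the background subtracted (0.119), on the Cy5 arrays alone (0.0836) and without the 4 brightest arrays (0.171). As labelled they differed by 0.30, 0.09 and -0.13. Without 3 µM THC at 24 h in either experiment, 0 clones differed between doses as headed with the block. It was also 0 without the 4 brightest arrays and with all negative flags left out, 1 with the background subtracted, and between 0 and 8 over all 15 settings. The other replicates left out in turn gave between 1 (vehicle at 24 h) and 16 (5 µM THC at 24 h in experiment 1).

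Vehicle at 8 h against 0 h gave 0 clones past the threshold as labelled with 1276 at an unadjusted p under 0.05. Vehicle at 24 h gave 0 with 1551, and both lay above the 559 of chance. The lowest adjusted p as labelled was 0.307 and 0.225. As headed without the block, vehicle gave 1 clone with 699 at 8 h and 0 with 651 at 24 h. If the channel headings miss the dye swap, a dye effect common to all arrays would stay in the values as labelled. The excess as labelled is therefore not settled as change since 0 h. As labelled, the replicates of all groups correlated with one another at a median of 0.56 across clones, and the 2 experiments of vehicle at 24 h at 0.73, close to the 0.79 between vehicle and 5 µM THC at 24 h in experiment 1. As headed, the 2 experiments of vehicle correlated at -0.01 at 8 h and 0.62 at 24 h. As labelled, the counts of vehicle against 0 h moved with the settings. Fitting vehicle alone, so that the spread rested on only 2 replicates, gave 1241 at 8 h and 2201 at 24 h. Array quality weights gave 298 and 3101, and subtracting the background gave 158 at 24 h.

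The effects of 5 µM THC at 8 and 24 h correlated at -0.004 across clones as labelled and 0.13 as headed. Taking the times from different experiments gave 0.03 and 0.12 as labelled, and 0.31 and -0.01 as headed, so the likeness as headed was not seen both ways. In 100 simulations with no effect the correlation as headed reached at most 0.05, but these leave out the deviations that replicates of one experiment share. For 3 µM the values were -0.04 as labelled and -0.33 as headed, and with the times from different experiments 0.03 and 0.16 as labelled, and -0.35 and -0.13 as headed. Between the 2 doses at the same time, which share vehicle replicates, simulations with no effect gave 0.50. At 24 h the doses correlated at 0.32 as labelled and 0.67 as headed. The covariance as headed was 0.0396 against 0.0281 simulated. At 8 h the correlation was -0.11 as labelled and 0.67 as headed, with a covariance as headed of 0.0334 against 0.0280. Part of this likeness may come from the shared vehicle replicates. Taking 5 µM from one experiment and 3 µM from the other, which share neither vehicle nor reference, gave 0.40 and 0.41 at 24 h and 0.22 and 0.01 at 8 h as headed. As labelled the values were -0.02 both ways at 24 h, and -0.12 and -0.50 at 8 h.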

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

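The tests of the dye orientations and of the print blocks were chosen after the results were seen, except the share of bad flags, whose bound was written before. The splits of the replicates were planned.

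The number of clones above the blank spots stood apart on 1 array in each of 2 groups, 10132 for vehicle at 8 h in experiment 1 with the sample in Cy5 and 5460 for 3 µM THC at 24 h in experiment 1 with the sample in Cy3. In all 15 tests were made, of 3 measures in each of the 5 groups with 4 arrays, and by chance about 1 test in 20 would stand out. Spots outside the tested ID classes also carried signal: over the arrays a median of 96.7% of the 152 spots of class m and 72.7% of the 352 spots of class x exceeded the level set by the blank spots, against 11.9% of the blank spots themselves. No group effect was tested on them.

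The opposite course of the 2 dye orientations of a replicate held in all 11 pairs. A dye effect that each clone has on all arrays is argued against, since it cancels in a difference within one dye, yet these differences had a median correlation of -0.77 between the Cy5 and Cy3 arrays. A candidate explanation is that channel headings or dye labels fail to follow the swap on 1 array of each pair: with no array turned, the experiments correlated at 0.67 for 5 µM THC at 24 h, and higher than as labelled in 3 of the 4 comparisons. Correlations between whole replicates are mixed and cannot decide this. If the headings miss the swap, a dye effect common to all arrays would stay in the mean as labelled and raise them. With no array turned, the median correlation between replicates was 0.30 against 0.56 as labelled. That between the experiments of a group fell for vehicle at 8 h (0.59 to -0.01), 3 µM THC at 8 h (0.55 to -0.37) and vehicle at 24 h (0.73 to 0.62). It rose for 5 µM at 8 h (-0.28 to -0.01), 3 µM at 24 h (0.26 to 0.34) and 5 µM at 24 h (0.68 to 0.72). Dye effects that differ from one labelling to the next stay open: pair means of 2 replicates correlated as low as -0.45 with no array turned, the labels name no labelling round, and no biological explanation was tested. If such dye effects are the source, the clones called as headed need not reflect expression.

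In the 9 blocks of 2 arrays of 3 µM THC that lay under 0.5, a spot grid laid 1 step off may be the source, since reading each block 1 row away, in some blocks with 1 column as well, brought its correlation with the other arrays to at least 0.64. For the 2 such blocks on arrays of 5 µM THC at 8 h, the best step of 1 was by column. It left their correlations lower, at 0.2 against 0.38 as read and 0.078 against 0.12, which argues against a grid laid 1 step off there. Larger shifts were not tried. Spots marked bad stay open for those blocks: they made up 37% of their spots, 52.4% of one block and 21.7% of the other, between the bounds set beforehand. Leaving out all 11 blocks gave 0 clones as labelled in all 9 comparisons and 115 for 5 µM THC at 24 h as headed with the block, 114 of them among the 121.

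For THC over both doses and times, the real split gave 0 clones, and the highest count among the other splits was 0. No split can give fewer, so the figure of 100 of the 100 splits drawn from 225 with as many follows from the real count of 0 and says nothing about chance. At an unadjusted p under 0.05 the real split gave 83 clones, and 99 of the 100 splits gave at least as many, up to 1362.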

How the results depend on the processing

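Settings named as headed, the authors' own signs, blocks left out, bright arrays left out and clones with flag 0 were added after seeing the data; the others were planned. As labelled, the 7 THC and dose comparisons stayed at 0 clones in 100 of 105 planned fits with all replicates and in 40 of 48 with 1 left out. The replicate block left all of them at 0. The cause of the changes below was not tested. Cy5 arrays alone gave 7 clones for 5 µM at 24 h, 1 for 5 µM at 8 h, 1 for 3 µM at 8 h, 1 for the difference between times, and 1 and 3 for vehicle at 8 and 24 h. Subtracting the background gave 1 for 3 µM at 8 h and 158 for vehicle at 24 h. For vehicle at 8 h print-tip loess gave 1, and scaling between arrays gave 10 at 24 h. Fitting vehicle alone, on only 2 replicates, gave 1241 and 2201. Array quality weights gave 298 and 3101, and arrays as separate values 100 and 375, with a correlation within replicates of -0.365. With replicates left out, counts lay between 0 and 1 for 3 µM at 24 h (1 without its experiment 2), 0 and 59 for 5 µM at 8 h (59 and 2 without its experiment 2 and 1, 5 without vehicle 2), 0 and 83 for 3 µM at 8 h (83 without its experiment 2, 7 without vehicle 2), 0 and 2 for the time difference (vehicle 2 at 8 h), 0 and 7 for the dose difference (3 µM at 8 h, experiment 2), and 0 to 11 and 0 to 3 for vehicle at 8 and 24 h (without their experiment 2); for 5 µM at 24 h and both doses and times they stayed at 0. Without the 4 arrays of over 30% flag 0, 12 clones passed for 5 µM at 8 h. The authors' signs gave 2 for 5 µM at 24 h among 1942 clones and 25 for both doses and times among 3059.

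As headed without the block, 10 clones passed for 5 µM at 24 h, 2 for the dose difference and 1 for vehicle at 8 h; with the replicate block the first rose to 121, the dose difference to 5, and 5 µM at 8 h gave 5. Over 15 other settings as headed the 121 ranged from 10 to 695, above 0 in all 15, and with 1 replicate left out from 3 to 202. The replicates that moved it by over 1.5 times were vehicle at 8 h (78 without either experiment), 5 µM at 8 h (75), 3 µM at 8 h (202), 3 µM at 24 h (40), vehicle at 24 h in experiment 2 (3) and 5 µM at 24 h in experiments 1 (34) and 2 (3). Without the 4 bright arrays it was 29, with background subtracted 79, with array weights 695 and with scaling between arrays 194. None of these 4 bright arrays was of 5 µM THC or vehicle at 24 h. Without them the 4 clones named for that comparison kept their differences (2.78, 2.50, -2.45 and -2.32). The drop to 29 therefore came through the shared spread, to which the other groups contribute. The count of 5 for 5 µM at 8 h ranged from 0 to 59 over the 15 other settings. The 59 came with the authors' log2 table, where 2 of the 5 clones were measured and 1 was among the 59. It also moved with a replicate left out, as given above. 4 of the named clones changed sign as labelled: IMAGE:208718 to -0.050, IMAGE:417504 to 0.10, IMAGE:3528619 to 0.10 and IMAGE:4110925 at 8 h to -0.060. In 81 further fits a named clone kept its sign but missed the threshold, and in 126 it kept both.

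The correlation of 8 h with 24 h moved by more than its spread between experiments for 5 µM to 0.26 with scaling, 0.16 without negative flags, 0.20 on Cy5 arrays and 0.35 with the authors' signs, and for 3 µM to -0.16 on Cy5 arrays, 0.18 without the bright arrays, -0.19 on clones with flag 0, 0.59 with the authors' signs and -0.33 as headed, with or without the block. With replicates left out it ranged from -0.11 to 0.12 at 5 µM and from -0.13 to 0.18 at 3 µM. Signal over background limits the dim spots: a median of 15.6% of spots had flag 0. The test at gene level, the gene lists and a slide batch were not run.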

Other observations

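The comparison of clone signs across doses and times was chosen after the result was seen. The 121 clones past the threshold for 5 µM THC at 24 h as headed with the block were set against the earlier time, which shares no replicate with 24 h. At 5 µM and 8 h, 108 of the 121 had the same sign, with a median log2 difference of 0.35 in the direction of 24 h. These clones were picked for their calls at 24 h: over all tested clones the effects of 5 µM at 24 and 8 h correlated at 0.13, at 0.31 for 24 h in experiment 1 with 8 h in experiment 2, and at -0.01 the other way round. At 3 µM and 8 h, 84 had the same sign, with a median of 0.08. At 3 µM and 24 h, which shares the vehicle replicates, 118 did, with a median of 0.37. Sharing alone brings such likeness, and its size under no effect was not computed for these clones. The difference between times was past the threshold for 0 clones in both readings, but as headed for 10 without vehicle at 24 h in experiment 1 and for 2 with the background subtracted.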
